A study of Mus musculus with 5 samples.

How the data were processed

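Gene expression was measured by RNA sequencing in 5 libraries of mouse common myeloid progenitors, blood progenitor cells that give rise to granulocytes, monocytes, red cells and platelets. The cells carried loxP-flanked (floxed) Mll1 alleles and had been transformed with a retroviral vector that expresses the leukaemia gene MN1 together with GFP. Per the labels, 3 libraries came from cells given a control vector and 2 from cells given Cre recombinase, labelled Mll1 knockout, and cells were sorted at day 7. RNA was prepared as stranded mRNA libraries, per the labels' protocols. The labels do not say whether replicates came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical. A design text of the series also names Dot1l floxed and knockout cells, which were not analysed here.

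The deposited values are FPKM, fragments scaled to gene length and to the mapped fragments of the library, with 1 value per Ensembl gene and library and 31626 genes in each file. The submitters' processing notes name CASAVA 1.8.2, GSNAP, SAMtools and Cuffdiff, and the mouse build mm9. The gene annotation, the handling of reads that map to several places, the use of strand in the counting and the Cuffdiff version are not given in the sources used here. Genes with near-identical copies are therefore uncertain: Gapdh stood at 2.04 ± 0.375 FPKM (SD, n = 3) in the controls, and 26 of the 77 ribosomal protein genes tested were below 10 FPKM, although genes of both kinds are usually abundant. Genes that overlap another gene on the opposite strand are uncertain too; besides those named as such beside their values, they include Cd27, Prtn3, Alas2, H2-DMa, Cdc20, Tap1, Sez6l and B4galnt3. Hoxa5 overlaps Hoxa3 in the annotation. In 16 genes at least 1 library held the value 999999999, which is no FPKM. These were treated as failed estimates and the genes were left out, among them Eno1, Eif4g1, Son and Ccne2. Control replicate 1 also listed 11672 genes at 0, and the other libraries listed between 12695 and 13061.

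Absolute depth is unknown, because the files hold no counts. Relative depth was read from genes below 2 FPKM in every library, whose values step by the worth of 1 read. Against control replicate 1, the commonest ratio was 0.994 and 1.018 in control replicates 2 and 3 and 0.98 and 0.981 in the knockout libraries. About 30% of the genes compared lay, within 0.3%, at ratios of 1 to 3 reads (29.1% to 30.3%), against 0.998% to 1.57% at shifted ratios.

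Genes with at least 1 FPKM in at least 2 of the 5 libraries were kept (11780 genes). The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. Log2 changes are knockout minus control on the log2(FPKM + 1) scale, which understates the change of low genes. The level of Mll1 was also tested by a two-sided exact permutation of the 5 libraries over 10 splits. Before the data were examined, 21 gene lists were fixed, covering Hox clusters, self-renewal, blood lineages, stress, handling and housekeeping. Lists with at least 3 tested members (20 of 21) were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. List members were counted over all genes tested and adjusted over the list alone. Symbols are those of the files; 26622 gene IDs matched GENCODE M21, which was used only for current symbols, gene type, transcript length, GC content, overlaps and neighbours.

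Genes were named by a rule fixed before the data were examined. It took Mll1; the 12 largest rises and the 12 largest falls past the threshold whose knockout values both lay outside the range of the controls, leaving out genes without a proper symbol; up to 4 members of each list with the smallest p; and a set of always-named myeloid and MLL1-linked genes. Values of some genes that this rule takes are not reported here. The limma step was tested on data simulated for this comparison. In each of 20 runs, 200 of 11780 genes were changed and a further list of genes was shifted. Of the 200, it recovered 73.8% of changes of 1 and 93.8% of changes of 2 on the log2 scale, with 4.85% false among the calls. The simulated errors were independent between genes and had the same spread in both groups, taken from the fit itself. The simulation therefore does not cover a library that stands apart, as control replicate 1 did. Alternatives covered the pseudocount, the filter, the scaling, the empirical Bayes step, the replicate number as a block, each library left out in turn, the list test, rows that share a symbol and the threshold. After the data had been seen, 3 more were added: protein-coding genes alone, failed estimates as missing values, and a loess correction for transcript length and GC content.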

Results

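The data are FPKM values of 5 libraries of MN1-transformed mouse common myeloid progenitors, 3 with intact Mll1 and a control vector and 2 given Cre to delete Mll1. MN1 is a transcriptional cofactor that transforms these progenitors, and Mll1 (current symbol Kmt2a) encodes a histone H3 lysine methyltransferase that maintains Hox gene expression. Absolute depth is unknown, and the worth of 1 read in the other libraries was between 0.98 and 1.018 of that in control replicate 1. The design has a single comparison, which asks what loss of Mll1 does to gene expression in these cells. No library of cells with wild type Mll1 given Cre was analysed here, so Cre exposure and loss of Mll1 go together in this comparison.

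The targeted gene was lower in both knockout libraries than in each control. Mll1 stood at 9.67, 7.28 and 7.19 FPKM in control replicates 1, 2 and 3 and at 6.22 and 5.32 FPKM in knockout replicates 1 and 2, a log2 change of -0.41. The exact permutation test gave p = 0.1, the smallest that 10 splits allow, and limma an adjusted p of 0.158. The labels do not state which exons are floxed, so an FPKM over the whole gene need not show the deletion. The mouse gene Mn1 stood at 81.0 ± 10.5 FPKM (SD, n = 3) in controls and 74.3 ± 4.57 FPKM (SD, n = 2) in knockouts, with an adjusted p of 0.601. Reads of the MN1 vector may enter these values, so they need not measure the endogenous gene. Dot1l, which encodes the H3 lysine methyltransferase of the series' other design, stood at 22.1 ± 1.1 and 22.3 ± 0.193 FPKM, with an adjusted p of 0.934.

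Genes of the HoxA cluster, transcription factors that keep myeloid progenitors immature, fell in the knockout libraries. Hoxa9 fell from 18.9 ± 2.02 to 6.74 ± 0.343 FPKM (limma adjusted p = 0.00853), Hoxa7 from 5.49 ± 1.02 to 0.835 ± 0.121 FPKM (adjusted p = 0.0125) and Hoxa5 from 1.92 ± 0.228 to 0.214 ± 0.0107 FPKM (adjusted p = 0.0156). These 3 were the members called among the 6 tested, and all 6 passed, downward, when adjusted over the list alone. Hoxa10 stood at 26.3, 9.43 and 10.4 FPKM in the controls and at 3.74 and 3.84 FPKM in the knockouts, and its adjusted p was 0.0832. Hoxa11 stood at 14.5 ± 5.52 and 4.93 ± 0.425 FPKM, with an adjusted p of 0.0525. The list median over these 6 of 11 genes was -1.35 (camera adjusted p = 0.000268, and adjusted p = 0.322 with an estimated correlation). It was -0.61 with no filter on low values and -0.89 with a pseudocount of 5. None of the 22 genes of the other Hox clusters was kept, and their highest value in any library was 0.122 FPKM.

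Self-renewal genes linked to MLL1 outside the Hox clusters were lower as a group, led by Flt3, the receptor tyrosine kinase of early progenitors. Flt3 fell from 91.0 ± 6.70 FPKM to 8.60 ± 1.29 FPKM, which is 10.6-fold lower (adjusted p = 0.00362). The transcription factor gene Mef2c fell from 22.7 ± 6.22 to 3.43 ± 0.0496 FPKM, Zfp521 from 20.1 ± 0.625 to 5.44 ± 0.510 FPKM, and Bcl2, which encodes an inhibitor of cell death, from 11.3 ± 1.85 to 3.34 ± 0.0245 FPKM. Of the 22 members tested, 9 fell and 1 rose, and adjusted over the list alone 12 fell and 1 rose. The member that rose was Lmo2, from 147 ± 18.2 to 255 ± 4.35 FPKM. Meis1, the partner of Hoxa9, stood at 9.45 ± 2.61 and 6.34 ± 1.15 FPKM and was not called (adjusted p = 0.269). Pbx3 (adjusted p = 0.103), Cdk6 (adjusted p = 0.0595) and Myc (adjusted p = 0.294) were not called either. The list median was -0.56 (camera adjusted p = 0.000193, and adjusted p = 0.322 with an estimated correlation). Evi1 (Mecom) was below the filter, at 0.671 ± 0.119 FPKM in controls and 0.0916 ± 0.0613 FPKM in knockouts.

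**Figure D1:**
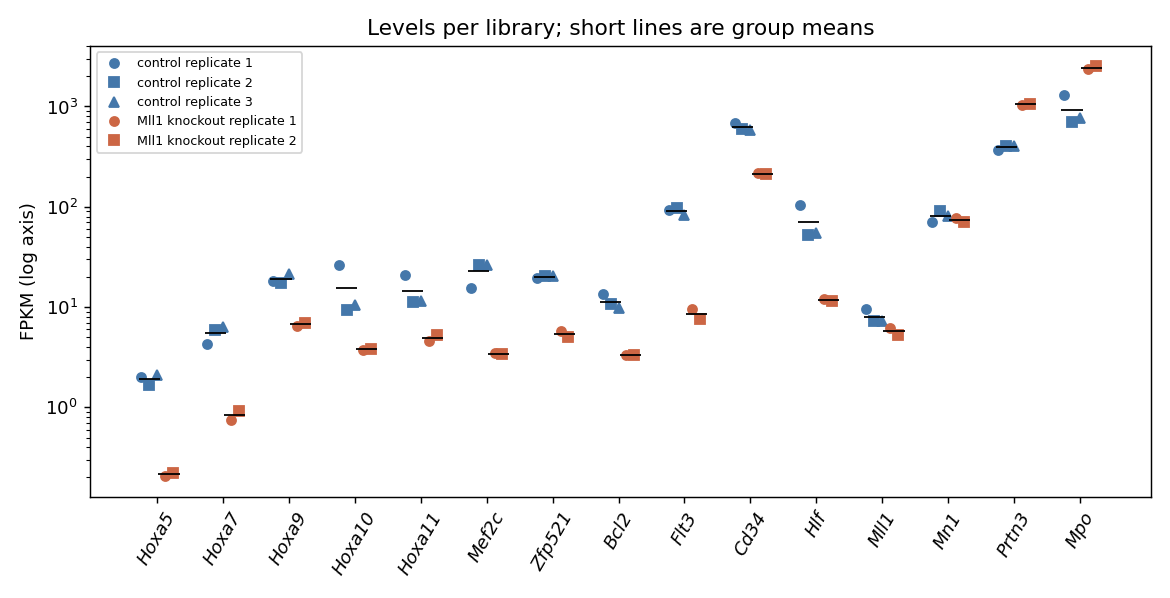
FPKM on a log axis of 15 genes in each of the 3 control (blue) and 2 Mll1 knockout (orange) libraries, with group means as short lines. Flt3 fell from a mean of 91.0 to 8.60 FPKM and Prtn3 rose from 393 to 1048 FPKM, while Mn1 stood at 81.0 and 74.3 FPKM. Reads of the MN1 vector may enter the Mn1 values.

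Markers of stem and progenitor cells also shifted downward. Cd34, a surface sialomucin of progenitors, fell from 624 ± 53.2 to 214 ± 3.42 FPKM (adjusted p = 0.00657), Cd27 from 33.1 ± 3.63 to 5.69 ± 0.812 FPKM and the transcription factor gene Hlf from 70.3 ± 28.4 to 11.8 ± 0.455 FPKM. Of the 18 members tested, 9 fell and 1 rose, and adjusted over the list alone 11 fell and 2 rose. Gata2, a transcription factor gene of stem and mast cells, was the 1 that rose, from 50.1 ± 2.17 to 65.6 ± 2.54 FPKM. The list median was -0.49 (camera adjusted p = 0.0014, and adjusted p = 0.443 with an estimated correlation).

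The list of genes of promyelocytes and their primary granules, which also holds the transcription factor genes Cebpa and Cebpe, was higher as a group in the knockout libraries. Prtn3, which encodes proteinase of the azurophil granule, rose from 393 ± 21.7 to 1048 ± 29.6 FPKM (adjusted p = 0.00684), Mpo, which encodes myeloperoxidase, from 924 ± 331 to 2447 ± 88.0 FPKM (adjusted p = 0.0469) and Serpinb1a from 244 ± 6.05 to 399 ± 2.88 FPKM. Of 14 members, 7 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell. The member that fell was Nkg7, a granule gene of cytotoxic lymphocytes, from 143 ± 23.1 to 75.5 ± 6.18 FPKM. The list median was 0.76 (camera adjusted p = 0.00143, and adjusted p = 0.322 with an estimated correlation).

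Mature neutrophil genes had a list median of 1.32 (camera adjusted p = 3.08e-07, and adjusted p = 0.4 with an estimated correlation). The median was 2.02 with a pseudocount of 0.1. Of 24 members, 4 rose and none fell over all genes tested, and adjusted over the list alone 11 rose and none fell. The 4 were Trem3 (26.3 ± 2.14 to 67.9 ± 1.13 FPKM, adjusted p = 0.00656), Anxa1 (59.5 ± 9.24 to 139 ± 2.31 FPKM), Il1b (2.12 ± 0.411 to 5.19 ± 0.00986 FPKM) and Lcn2 (100.1 ± 31.6 to 261 ± 2.39 FPKM). Control replicate 1 differed from the other controls in this list, with a median 1.57 higher than their mean on the log2 scale. S100a8, an abundant calcium-binding protein gene of neutrophils, stood at 3129, 347 and 485 FPKM in the controls and at 11790 and 10990 FPKM in the knockouts. Camp, an antimicrobial peptide gene of secondary granules, stood at 43.0, 1.35 and 2.01 FPKM in the controls and at 33.3 and 32.4 FPKM in the knockouts, so control replicate 1 held the highest value. Itgam, the integrin CD11b, stood at 15.2, 4.78 and 3.93 FPKM in the controls and at 18.4 and 17.6 FPKM in the knockouts (adjusted p = 0.185).

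**Figure D2:**
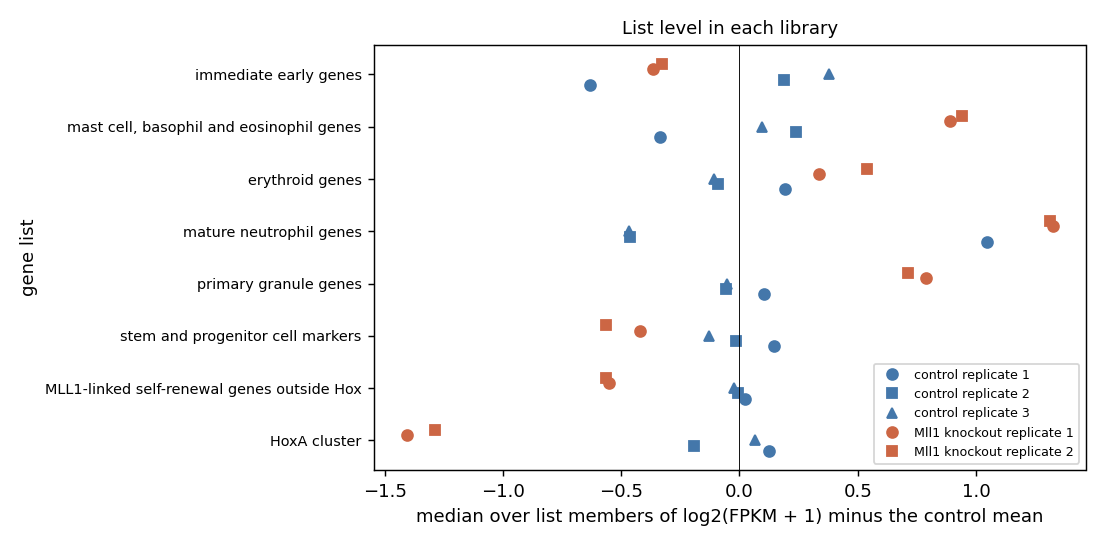
Level of 8 gene lists in each library, as the median over members of log2(FPKM + 1) minus the control mean of each gene, for 3 control (blue) and 2 Mll1 knockout (orange) libraries. In the mature neutrophil list control replicate 1 lies at 1.05, near the knockouts at 1.33 and 1.31, while in the HoxA list the knockouts lie at -1.41 and -1.29 and the controls between -0.19 and 0.12.

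Other blood lineages moved in different directions. Erythroid genes had 6 members that rose and 1 that fell of 13, and 7 and 1 adjusted over the list alone. Gata1, the erythroid transcription factor gene, rose from 9.43 ± 0.506 to 14.4 ± 0.344 FPKM, and Alas2, the first enzyme of haem synthesis in red cells, from 0.790 ± 0.236 to 4.28 ± 0.243 FPKM. The median was 0.47 (camera adjusted p = 0.0014, and adjusted p = 0.443 with an estimated correlation), or 0.80 without control replicate 1. Without genes under a mean of 5 FPKM the median was 0.30 and the camera adjusted p 0.435. A pseudocount of 5 gave a median of 0.26. The globin gene Hba-a1 was not called, at 4.84 ± 7.80 and 1.86 ± 0.467 FPKM. Mast cell, basophil and eosinophil genes had 3 of 12 members that rose and 5 adjusted over the list alone. Their list median was 0.93 (camera adjusted p = 0.00123, and adjusted p = 0.322 with an estimated correlation), or 0.56 without control replicate 1 and 0.41 with no filter. Mcpt8, a basophil protease gene, rose from 17.3 ± 2.46 to 43.9 ± 3.21 FPKM and Il1rl1, the IL-33 receptor gene, from 14.6 ± 3.17 to 36.3 ± 1.84 FPKM. In the median of this list, control replicate 1 stood at -0.33 and control replicates 2 and 3 at 0.24 and 0.09.

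Monocyte and macrophage genes split. Irf8, a transcription factor gene of monocytes and dendritic cells, fell from 5.03 ± 0.574 to 0.802 ± 0.0340 FPKM and the chemokine receptor gene Ccr2 from 17.5 ± 1.64 to 6.26 ± 0.463 FPKM. Fcgr3, an Fc receptor gene shared with neutrophils, rose from 78.7 ± 8.89 to 216 ± 2.66 FPKM. These were the 3 members called of 16, over all genes and adjusted over the list alone (1 rose, 2 fell), and the list was not called (camera adjusted p = 0.298). Control replicate 1 stood 0.80 above the other controls in the median of this list, and without that library the list's adjusted p was 0.0116. Of 3 lymphoid genes tested, Thy1 fell from 45.3 ± 9.04 to 4.30 ± 0.738 FPKM and Rag2 from 3.01 ± 0.519 to 0.553 ± 0.0644 FPKM, both also adjusted over the list alone; Rag2 overlaps a gene on the opposite strand. The lymphoid median over these 3 of 24 genes was -1.36 (camera adjusted p = 0.0155, and adjusted p = 0.322 with an estimated correlation). It was -0.098 with no filter, -0.53 with a pseudocount of 5 and -2.24 with a pseudocount of 0.1. Megakaryocyte and platelet genes had 3 of 12 members that fell and 4 adjusted over the list alone, among them the integrin gene Itgb3 (19.7 ± 1.30 to 6.72 ± 0.0868 FPKM), with a median of -0.23 and a camera adjusted p of 0.0515. The call of this list depended on the setting: its adjusted p was 0.0194 in fry and 0.443 in camera with an estimated correlation. In camera at the preset correlation it ran from 0.0128 without knockout replicate 1 to 0.408 with no filter. Its median ran from -0.38 (without knockout replicate 1) to -0.081 (with no filter). Of 4 dendritic cell and MHC class II genes, H2-DMa fell from 43.5 ± 5.40 to 12.6 ± 1.12 FPKM, 2 fell adjusted over the list alone, and the adjusted p was 0.0967 in camera, 0.0441 in fry and 0.462 in camera with an estimated correlation. The median was -0.88, or -0.39 with a pseudocount of 5 and -0.027 with no filter.

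**Figure D3:**
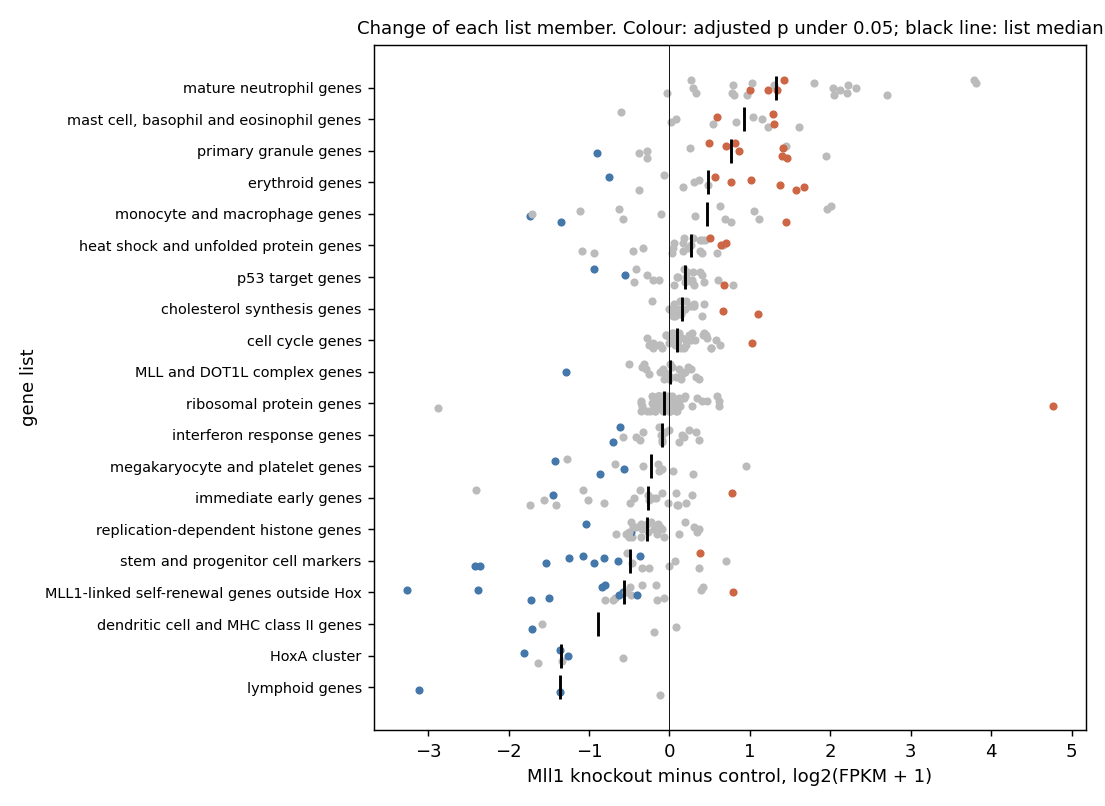
Log2 change (knockout minus control) of every tested member of the 20 lists, with list medians as black lines, and members called at an adjusted p under 0.05 in orange (rose) or blue (fell) and others in grey. Medians run from -1.36 for lymphoid genes and -1.35 for the HoxA cluster to 1.32 for mature neutrophil genes; with no filter on low values the lymphoid median was -0.098 and that of the HoxA cluster -0.61.

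Across all 11780 genes tested, 450 rose and 703 fell in the knockout libraries at an adjusted p under 0.05 in limma. Of these, 349 changed at least 2-fold on the log2(FPKM + 1) scale (139 rose, 210 fell). Among the largest rises were Cd2, a lymphocyte adhesion receptor gene, at 0.0355, 0 and 0 FPKM in the controls and 8.43 and 8.10 FPKM in the knockouts, the cytochrome P450 gene Cyp2a5 (0.430 ± 0.0304 to 9.26 ± 1.55 FPKM) and the iron exporter gene Slc40a1 (3.20, 0.577 and 0.865 FPKM in the controls, 12.1 and 12.2 FPKM in the knockouts). Olfml2b, Sez6l, B4galnt3, Dgat2, Gatm, Mgam, Ctse and Acpp completed the rises, with log2 changes from 2.16 for Acpp to 2.95 for Olfml2b, apart from Rpl41, which was listed at 0 in the controls and stood at 18.5 and 37.1 FPKM in the knockouts. The number of reads behind the values of Rpl41 is unknown and may be small. The largest falls besides Flt3 and Thy1 included Igfbp7 (31.0 ± 10.5 to 2.85 ± 0.802 FPKM), Lypd6b (13.3 ± 1.86 to 0.820 ± 0.000854 FPKM), the prostaglandin-degrading enzyme gene Hpgd (527 ± 170 to 70.0 ± 8.86 FPKM) and Nrgn (72.7 ± 2.82 to 11.4 ± 0.948 FPKM). Ddx4, Tgm3 and Ptgds also fell, with log2 changes of -2.91, -2.70 and -2.62. Control replicate 1 held the highest control value of several of these genes: 8.04 FPKM against 1.49 and 2.01 FPKM for Olfml2b, 16.2 against 4.57 and 6.84 FPKM for B4galnt3, 34.0 against 14.1 and 16.1 FPKM for Dgat2, and 2.99 against 0.597 and 0.780 FPKM for Acpp. Among the falls it stood at 42.8 against 12.8 and 11.8 FPKM for Ddx4, 38.3 against 15.1 and 16.1 FPKM for Tgm3 and 16.7 against 8.13 and 4.68 FPKM for Ptgds. Zfyve28 stood at 23.6, 37.0 and 14.6 FPKM in the controls and was listed at 0 in both knockouts. P2rx3 (42.1 ± 14.9 to 0.964 ± 0.150 FPKM), Lrrc43 and Igfbp7 overlap a gene on the opposite strand, so reads of the partner may enter their values.

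These counts moved with each library left out. Without control replicate 1, 1398 genes rose and 2118 fell, among them all 1153 genes called with every library; without control replicate 2, 45 and 66; without control replicate 3, 70 and 134; without knockout replicate 1, 3 and 4; and without knockout replicate 2, 0 and 0 in limma, with 1669 genes at an unadjusted p under 0.05. The share of calls that rose was 39% as tested, 49% after median-ratio scaling (597 and 621) and 51.7% after the length and GC correction (782 and 731), which was chosen after seeing the data.

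Stress, cell cycle and metabolic lists had a minority of members called, as had the genes as a whole (1153 of 11780). Of 24 p53 target genes, Tnfrsf10b rose (1.24 ± 0.114 to 2.59 ± 0.0989 FPKM) and Sesn1 and Tap1 fell, 3 rose and 2 fell adjusted over the list alone, and the camera adjusted p was 0.095 with a median of 0.19; the adjusted p was 0.0215 without control replicate 1 and 0.0102 with no filter on low values. Cdkn1a, the cell cycle inhibitor induced by p53, stood at 82.9 ± 10.1 and 108 ± 6.78 FPKM (adjusted p = 0.114). Cdc20, an activator of the anaphase-promoting complex, was the 1 cell cycle gene called of 39, also adjusted over the list alone, and rose from 89.3 ± 10.9 to 182 ± 8.28 FPKM. The cell cycle median was 0.10 (camera adjusted p = 0.00248, and adjusted p = 0.666 with an estimated correlation), or 0.17 after the length and GC correction, and fry did not call the list (adjusted p = 0.278). Without control replicate 1 its median was 0.042 and its camera adjusted p 0.0933, and after quantile normalization the adjusted p was 0.0601. The cell cycle median of control replicate 1 relative to the other controls was -0.21, larger in size than the change between groups. Heat shock and unfolded protein genes had 3 of 23 members that rose, Creld2, Sdf2l1 and Hsph1, with a median of 0.27 (camera adjusted p = 0.00201, and adjusted p = 0.443 with an estimated correlation); adjusted over the list alone 3 rose and 1 fell, and the list's adjusted p was 0.0743 in fry and 0.0504 in camera after quantile normalization. Cholesterol synthesis genes had 2 of 21 members that rose, also 2 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00248, and adjusted p = 0.462 with an estimated correlation). The fry test did not call this list (adjusted p = 0.144), and its median was 0.30 without control replicate 1, 0.25 without knockout replicate 1 and 0.063 without knockout replicate 2. Control replicate 1 stood 0.30 above the other controls in the median of this list, and the knockouts stood at -0.030 against that library. The rise of the cholesterol list therefore did not exceed the spread between controls.

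The remaining lists were not called by camera under the main settings. Interferon response genes had 2 of 19 that fell, Ifi47 and Parp14, and 4 adjusted over the list alone (camera adjusted p = 0.348). In the MLL and DOT1L complex list, Mllt3, a DOT1L partner gene, was the 1 called of 26, also adjusted over the list alone, and fell from 26.1 ± 0.880 to 10.1 ± 1.09 FPKM; the list's camera adjusted p was 0.787, with a median of 0.00051, which ran from -0.025 (without control replicate 2) to 0.087 (after the length and GC correction) over the alternatives, and a mean of -0.051. Of 23 immediate early genes, Egr3 rose and Egr1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.209), and the list median of control replicate 1 relative to the other controls was -0.95; without that library the median change between groups went from -0.26 to -0.42 and the adjusted p was 0.0213, and with a mean of at least 5 FPKM the median was -0.44. Replication-dependent histone genes had 2 of 27 that fell, 1 adjusted over the list alone (camera adjusted p = 0.0533). The call of that list depended on the setting: its adjusted p was 0.144 in fry and 0.666 in camera with an estimated correlation. In camera at the preset correlation it ran from 0.00942 without control replicate 1 to 0.194 with a mean of at least 5 FPKM. Its median was -0.27, and ran from -0.48 without control replicate 1 to -0.098 with a pseudocount of 5. Of 77 ribosomal protein genes only Rpl41 was called, over all genes and adjusted over the list alone (camera adjusted p = 0.873, with a median of -0.064 and a mean of 0.0012). That call may rest on a few reads. The ribosomal median was -0.027 after median-ratio scaling, 0.00067 without control replicate 2 and -0.0044 without knockout replicate 2.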

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

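The counts of changed genes moved with the libraries included. A lone knockout library was assumed to vary like the controls. Leaving out 1 library at a time gave 0 to 1398 genes that rose, 0 to 2118 that fell and 0 to 597 changed at least 2-fold. The replicate numbers share no stated meaning and there are 2 pairs, so they were not taken as pairing: deviations of same-numbered libraries correlated at 0.037 and 0.012, and with a replicate block 12 genes rose, 43 fell and 55 changed at least 2-fold, while the camera adjusted p was 0.0216 for megakaryocyte and 0.0421 for dendritic cell genes. Control replicate 3 has no partner, so the block fit rests on the 2 pairs alone. Its smaller counts need not reflect pairing. With no filter on low values (22571 genes tested) 238 rose, 259 fell and 194 changed at least 2-fold. A mean of at least 5 FPKM left 209 changed at least 2-fold. A pseudocount of 5 left 152 changed at least 2-fold, and a pseudocount of 0.1 gave 477. An adjusted p threshold of 0.1 gave 1021 that rose and 1414 that fell. Of the alternatives chosen after seeing the data, protein-coding genes only gave 677 that rose and the length and GC correction 782. The cause of the shifts other than the threshold was not tested. The 1153 called genes kept their direction wherever they were tested in the other fits compared gene by gene (all except the summed rows). In all 1153, both knockout values lay beyond every control value. Leaving out a library, or changing the pseudocount, the filter or the empirical Bayes step, could therefore not turn a direction. Of 74 named genes called, 74 kept the call without control replicate 1, 26 and 33 without control replicates 2 and 3, 3 and 0 without knockout replicates 1 and 2, 15 with a replicate block, 45 with no filter, and 66 or more in the other fits, apart from a mean of at least 5 FPKM (57 of 58 tested) and protein-coding genes only (73 of 73). The list calls numbered 11 in the camera test at the preset correlation, 9 to 14 under the other gene-level settings, 10 in fry and 0 with an estimated correlation (1 list at an unadjusted p under 0.05). In the MLL1-linked self-renewal and lymphoid lists the estimated correlation, -0.0015 and -0.0807, was below the preset of 0.01. Correlation between members does not account for the loss of those calls. In the other called lists the estimate was above the preset, from 0.0435 (mast cell, basophil and eosinophil) to 0.653 (cell cycle). The preset therefore allowed for less correlation in those lists than was estimated. With an estimated correlation camera takes its degrees of freedom from the 5 libraries rather than from the genes. Its power was therefore low, and a list it did not call is not shown to be unchanged. The log2 change of Mll1 stayed between -0.51 and -0.27, and its exact permutation p was 0.2 after quantile normalization. Unknown absolute depth limits what can be said of low genes.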

Other observations

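The tests of depth, of more mature cells, of the spread between controls, of Cre exposure and of short RNA genes were chosen after the results had been seen; the length and GC fit of control replicate 1 was fixed before its result was, and so was the odds ratio of the neighbours of Mll1, but not the use of its interval.

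Control replicate 1 stood apart from the other controls: 375 of 11780 genes differed there at least 2-fold from both, against 118 and 121 for control replicates 2 and 3, and it lay at 43.5 on the second principal component (27.3% of the variance) with the other libraries between -19.5 and -1.99.

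Mature neutrophil genes were among those that stood apart in control replicate 1, and 5 of the 6 list members S100a8, S100a9, Camp, Ngp, Ltf and Lcn2 were at least 2-fold higher there than in both other controls. A difference in depth was argued against by the worth of 1 read, which differed between control replicate 1 and the other controls by a factor of at most 1.018, and a length or GC bias by a fit that left the list median at 1.65 (1.57 before). A larger share of mature granulocytic cells may explain that library, but the separate stem and progenitor list was 0.217 higher rather than lower there, and a small share would hardly move it, so this stays open. Against control replicate 1 alone the knockout libraries were higher by a median of 0.451 on the log2 scale, with 17 of 24 members higher, which leaves open how much of the neutrophil change exceeds the spread between controls. In the HoxA list control replicate 1 stood 0.18 above the other controls, so a comparison with that library alone enlarges the fall, to a median of -1.42. Without control replicate 1 the HoxA median was -1.215, still larger in size than that difference between controls.

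Exposure to Cre cannot be told apart from loss of Mll1, because no library of cells with wild type Mll1 given Cre was analysed here. A DNA damage response to Cre would raise p53 target genes, whose list had a camera adjusted p of 0.095 and a median change of 0.194. Control replicate 1 stood 0.173 above the other controls in the median of that list, and the knockouts stood 0.059 above control replicate 1. The rise was thus of about the size of the spread between controls. That list was called, higher in the knockouts, with no filter on low values (adjusted p = 0.0102) and without control replicate 1 (0.0215), and over all alternatives its adjusted p ran from 0.0102 to 0.4. Loss of Mll1 itself is the biological explanation that the design names, and it was not tested apart from Cre.

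Calls in short RNA genes (18 of 369 tested) may rest on a few reads each. In 13 of the 18 the values were whole multiples of 1 read, within 0.03 of a read, against 1 of 1087 called protein-coding genes, and the median in the highest library was 5 reads, with the other genes taken as higher. No biological explanation was tested for them. Rpl41, at 18.5 and 37.1 FPKM in the knockouts, was listed at 0 in each control. It was in neither of these sets, so the check of whole reads did not cover it. Its call may rest on a few reads too.

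A hypothesis that genes beside Mll1 on its chromosome changed more often was tested on the 50 nearest tested genes, of which 3 were called (Il10ra, Thy1 and Sorl1) against 1150 of 11729 others, an odds ratio of 0.587 (95% interval 0.117 to 1.83, Fisher's exact p = 0.479). The odds ratio met the bound set beforehand for no such effect, under 1.5. The interval, taken into account only after the odds ratio had been seen, reaches above that bound, so the hypothesis is left open.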
